A study of Mus musculus with 37 samples.

How the data were processed

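Total RNA from the olfactory bulb, cortex, cerebellum and brain stem of 2 df/+, 3 +/+ and 3 dp/+ mice was hybridised to 37 Affymetrix gene-level arrays. The submitters' processing notes name RMA and Affymetrix Expression Console, without versions or library files. The authors' deposited values are log2 RMA summaries of 35556 probe sets, background-corrected and quantile-normalised across arrays by RMA. No label states the base of the logarithm, and base 2 was read from the values, which have the range of RMA output on all 37 arrays. The quartiles were not equal between arrays. The lower one ran from 6.14 on a +/+ cortex array to 6.55 on a dp/+ cerebellum array, and the upper one from 9.64 to 9.31 on the same arrays. All columns of the table were used. The labels give no hybridisation date or batch, so a batch could not be tested.

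Mouse, genotype and region were taken from the labels, which give 31 region samples of 8 mice. By the labels, 6 samples have 2 arrays, although the design text counts fewer, and these were averaged. The olfactory bulb of +/+ mouse 3 is represented by an array labelled as technical repeat 2 alone. A second array of 1 sample is not a replicate, and the 4 regions of 1 mouse are not independent, so the mouse was the unit of replication.

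Probe sets were named from the table supplied with the array. Of these, 21789 have 1 gene symbol, 1621 have several and 12146 have no listed gene. The probe set with the highest mean over all arrays stood for each gene, which gave 19938 genes. Of the identifiers with 1 symbol, 21698 were found in the reference gene table (GRCm38.p6) and 91 were not. That table was used for names and for which genes neighbour each other, and no coordinates are given, since the series names no genome build. By its gene order the 30 measured interval genes lie from Slx1b to Septin1 on chromosome 7.

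Across the brain, each gene had 1 value per mouse: the mean over that mouse's regions of its log2 value minus the +/+ mean of the region. limma 3.58.1 in R 4.3.3 (lmFit, eBayes) gave the slope on log2 copies, in which 1 is proportional to copy number, and the contrasts of df/+ and of dp/+ with +/+ in a model with genotype as 3 groups. Within regions, limma fitted a mean for each region and a slope within each region to all 31 samples, with the mouse as a random block (duplicateCorrelation, consensus correlation 0.15), and an F test compared the 4 slopes. Regional differences in +/+ mice were tested by an F test with the mouse as a fixed block. P values were adjusted by the method of Benjamini and Hochberg over all 19938 genes, with a threshold of 0.05. The slope of the mean of the interval genes was tested by an exact two-sided permutation test over all assignments of genotypes to mice. Counts adjusted over the list alone use the members of that list as the family of tests.

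Of 37 fixed gene lists, covering the interval, its flanks, cell types, brain regions, signalling, metabolism and a check of sex, 32 were tested by camera with an inter-gene correlation of 0.01, with an estimated correlation, and by fry. The interval, its flanks and the sex genes were tested apart, and red blood cells, with 2 measured genes, fell short of the minimum of 4. The main comparisons and their tests, the lists, the rule for naming genes and all alternatives but 1 were chosen before the data were examined. The comparison of the step from 1 to 2 copies with that from 2 to 3 was added later, and the closing section says which of its tests were chosen after the results were seen. The rule names every measured interval gene; in each comparison across the brain up to 10 genes outside the interval with the smallest p past the threshold; in each region, and for slopes that differ between regions, up to 5 such genes; of each list up to 4 members with the smallest p; and, where none passed, the 3 with the smallest p. Genes named beyond the rule are said to be chosen after their values were seen.

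Each choice was changed alone. The alternatives were the first array of each sample; every probe set as its own feature; brighter genes only, with a +/+ mean in some region above the median of all genes; quantile normalisation again within regions; arrays centred on their medians; a trended robust prior; array weights; a slope on the copies themselves; all region samples with mouse as a random block; the regions with all 8 mice; the biological replicate number as a block; no block for the mouse; each region fitted alone; the interval without its end genes or by gene order; adjustment over genes outside the interval alone; and each mouse left out in turn. Cyclic loess between arrays, with 3 iterations, was added after a rise of dim genes on dp/+ arrays was seen. Without 1 of the 2 df/+ mice, the remaining one is assumed to vary like mice of the other genotypes.

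The procedure was tested on simulated data with 19938 genes and the same samples. Across the brain it recovered 78.0% of genes with a slope of 0.25 and 100% with a slope of 0.5 or 1. In the cerebellum it recovered 99.0% at 0.5, and for a slope that differs between regions 86.0% at 0.5 and 100% at 1. Of 19538 unchanged genes it called 12, 18 and 9 in these comparisons. The simulated genes varied independently of each other, so these counts do not cover a structure of the samples that many genes share.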

Results

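Messenger RNA was profiled on 37 Affymetrix gene-level arrays from 4 brain regions of 8 male F1 hybrid mice (C57BL/6N:129Sv): the olfactory bulb, cortex, cerebellum and brain stem. The mice carried 1, 2 or 3 copies of the chromosome 7 segment that corresponds to human 16p11.2, whose loss and gain in people are linked to autism. The 2 df/+ mice carried the deletion on 1 chromosome, the 3 +/+ mice were wild type, and the 3 dp/+ mice carried the duplication. Each replicate is a separate mouse by the labels. The arrays cover 31 region samples, since 6 samples were hybridised 2 times and no cortex was profiled from dp/+ mouse 3. The same 35556 probe sets were read on every array, and the number of arrays limits the precision of each value. Probe sets with 1 gene symbol gave 19938 genes. Median technical SD between 2 arrays of 1 sample was 0.09 on the log2 scale, against a median SD of 0.13 between mice of 1 genotype and region. Xist lay between 4.78 and 5.18 and the Y-linked gene Eif2s3y between 9.16 and 10.17 (log2) in all 31 samples, as in males. Of the genes listed as markers of a region, 11 of 12 measured for the olfactory bulb, 7 of 8 for the cortex, 12 of 12 for the cerebellum and 14 of 14 for the brain stem were highest in their own region in +/+ mice.

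The first comparison asked whether expression of the interval genes follows their copy number. The mean expression of the interval genes was lower in df/+ mice and higher in dp/+ mice than in +/+ mice. Of the 33 listed genes 30 were measured, while Mapk3, Ino80e and Prrt2 had no probe set with 1 gene symbol. Averaged over the 30 measured genes, expression in df/+ mice was −0.56 ± 0.01 log2 relative to +/+ (SD, n = 2), or 67.9% of the +/+ level. In dp/+ mice it was 0.29 ± 0.003 log2 higher (SD, n = 3), or 122.2%. Both df/+ mice lay below all 3 +/+ mice, and all 3 dp/+ mice above them. The slope of the mean on log2 copies was 0.536, where 1 would be proportional to copy number (exact permutation test over the 560 assignments of genotypes to mice, two-sided p = 0.00179, the smallest that these assignments can give).

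**Figure D1:**
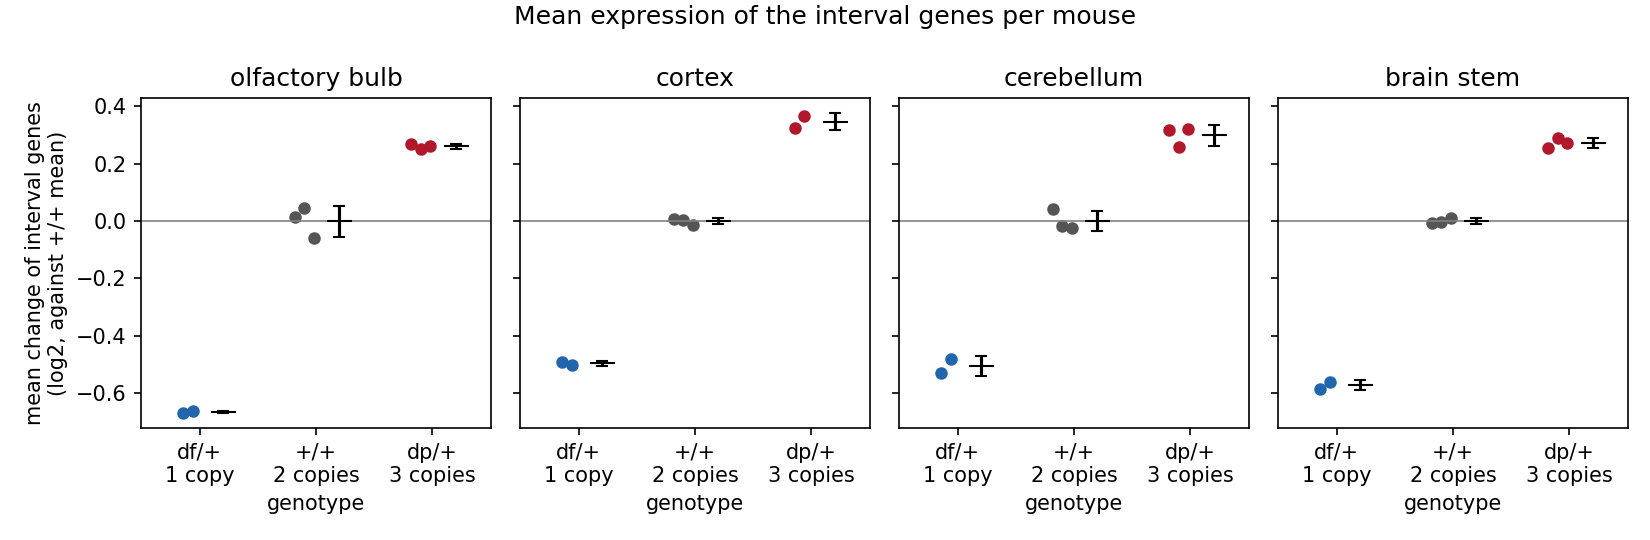
Mean change of the 30 measured interval genes in each mouse (log2, against the +/+ mean of the region), by genotype and region; points are mice, and the bars beside them are the mean and SD. The df/+ mice lie between −0.67 and −0.48 and the dp/+ mice between 0.25 and 0.37 in every region.

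Of the 30 measured interval genes, 21 had a dosage slope past an adjusted p of 0.05 across the brain, all 21 of them positive (limma). Adjusted over the list alone, 28 did, and all 30 slopes were above 0. The steepest after Gdpd3 was that of Pagr1a, a component of histone methyltransferase complexes, with 0.881 (95% interval 0.735 to 1.03). Taok2, a MAP kinase kinase kinase, had 0.776 ± 0.04 (SE, n = 8 mice), Ppp4c, the catalytic subunit of protein phosphatase 4, 0.740 ± 0.04, Cdipt, which makes phosphatidylinositol, 0.735 ± 0.04, and Kctd13, an adaptor for Cul3 ubiquitin ligases, 0.733 ± 0.06. Slx1b had 0.699, Sez6l2 0.673, Asphd1 0.662, Tbc1d10b 0.636, Tmem219 0.624, Maz 0.621, Ypel3 0.614, Cd2bp2 0.613, Tlcd3b 0.586, Doc2a 0.568, Coro1a 0.557, Bola2 0.492 and Hirip3 0.483. The lowest were those of Aldoa, a glycolytic enzyme among the most abundant messengers of the brain, with 0.401 ± 0.04, and of Mvp, the major vault protein, with 0.386 ± 0.05. Levels of these 21 genes in df/+ mice were 14.0% to 82.5% of +/+ (median 63.5%) and in dp/+ mice 111% to 155% (median 127%), where 50% and 150% would be proportional. For 19 of the 21, the 95% interval of the slope lay below 1. These slopes and percentages are those on the scale of the array. Its signal was not calibrated against known amounts of RNA, so whether RNA itself changed less than copy number was not tested. Coro1a was not past the threshold without df/+ mouse 1 (adjusted p = 0.16) or without df/+ mouse 2 (adjusted p = 0.0735), and Mvp was not without df/+ mouse 1 (adjusted p = 0.104) or with the biological replicate number as a block (adjusted p = 0.0643).

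Gdpd3, a lysophospholipase D, fell by more than its copy number in df/+ mice and was close to proportional in dp/+ mice. Its slope over all 3 genotypes was 2.21 (95% interval 1.86 to 2.55). Expression fell by 2.83 ± 0.10 log2 in df/+ mice (SE, n = 2), to 14.0% of +/+, and rose by 0.63 ± 0.09 log2 in dp/+ mice (SE, n = 3), to 155%. In the olfactory bulb it was 9.40 ± 0.35 (SD, n = 3) in +/+ mice, 5.56 ± 0.18 (SD, n = 2) in df/+ mice and 10.04 ± 0.13 (SD, n = 3) in dp/+ mice. In df/+ mice it read between 5.42 and 5.58 in all 4 regions, near the level of Xist in these males (up to 5.18), and was not tested against background, so the sizes of the fall and of the slope are those on the scale of the array. The step from 1 to 2 copies was steeper per log2 copy than that from 2 to 3 (adjusted p = 0.0201); no other interval gene passed that test, and 7 of the 30 had an unadjusted p below 0.05.

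The other 9 measured interval genes had slopes of 0.08 to 0.22 that did not pass the threshold over all genes, 7 of them with an unadjusted p below 0.05. They were Tbx6, a mesoderm transcription factor, Kif22, Zg16, AI467606, Qprt, an enzyme of NAD synthesis, Mylpf, a muscle myosin light chain, Spn, a leukocyte surface protein, Septin1 and 4930451I11Rik. Their median level stood at percentile 35 of all genes in +/+ brain, against 67.1 for the genes past the threshold.

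**Figure D2:**
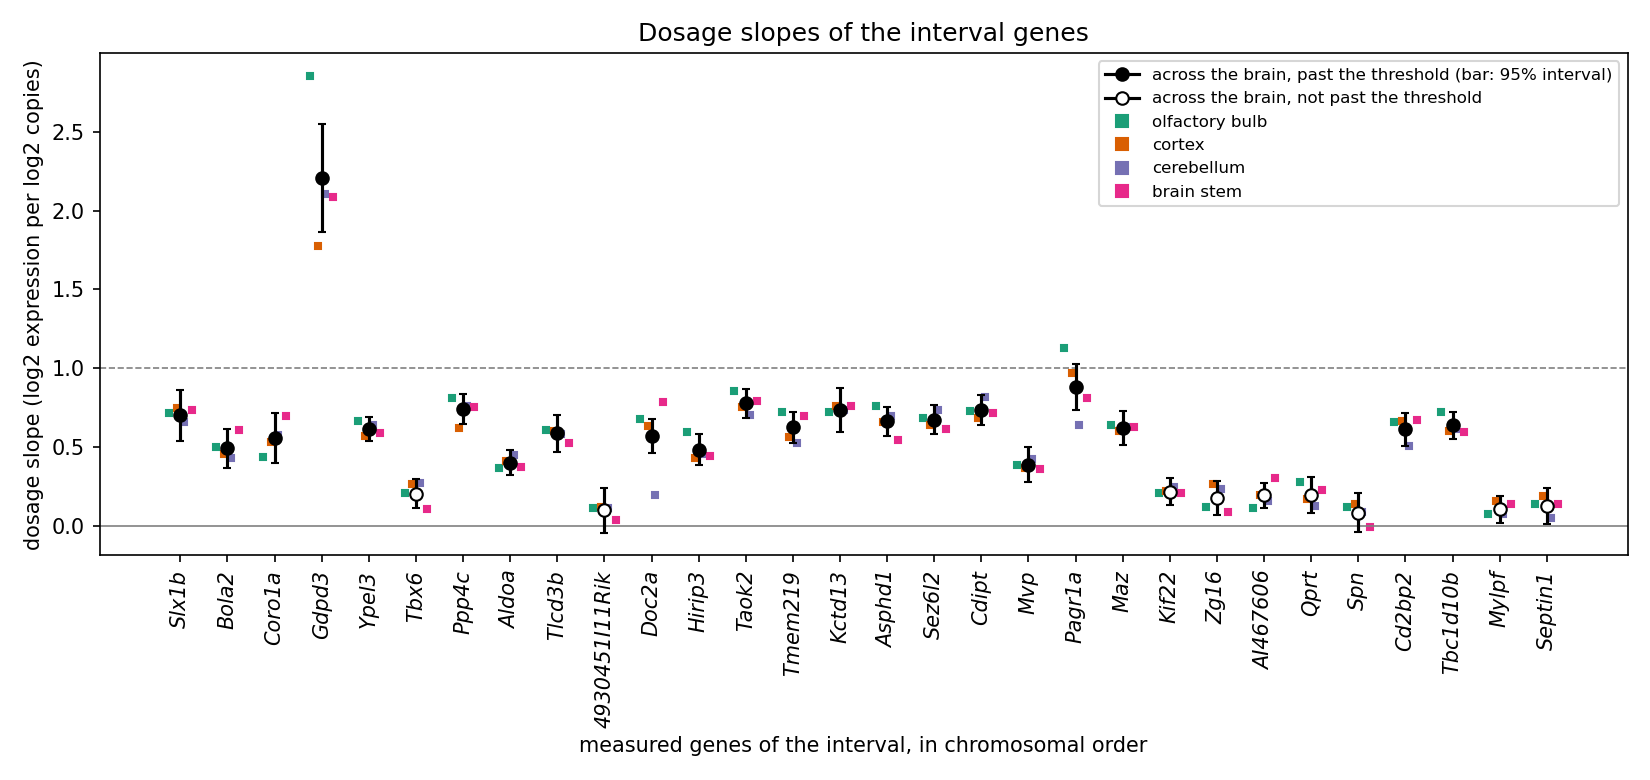
Dosage slope (log2 expression per log2 copies) of the 30 measured interval genes in chromosomal order; circles with bars are the slope across the brain with its 95% interval, filled where past the threshold, and squares are the slopes within each region. The dashed line marks proportionality, and Gdpd3 lies above it at 2.21 while 19 of the other genes past the threshold lie below it with their whole interval.

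Taken against +/+ mice alone, 19 interval genes fell in df/+ mice and 15 rose in dp/+ mice, with 0 called the other way; Spn and 4930451I11Rik were at 108% and 105% of +/+ in df/+ mice, neither past the threshold. Adjusted over the list alone, 24 were lower in df/+ mice and 27 higher in dp/+ mice. The 27 include Spn and Zg16, at 119% and 117% in dp/+ mice but 108% and 96.1% in df/+ mice. Spn and Zg16 stood at percentiles 35.3 and 9.08 of level, in the dim range that was higher on dp/+ arrays. The calls of dim genes in dp/+ mice therefore need not reflect dosage. In df/+ mice Pagr1a was at 51.3%, Slx1b at 54.0%, Ppp4c at 56.7% and Kctd13 at 57.1% of +/+. In dp/+ mice Taok2 was at 136%, Pagr1a at 135%, Sez6l2 at 133% and Tbc1d10b at 131% of +/+. The count in dp/+ mice was 3 without +/+ mouse 2, 7 without +/+ mouse 3, 7 without dp/+ mouse 1 and 3 without dp/+ mouse 2. It was 8 among brighter genes only, 4 with the biological replicate number as a block and 26 with array weights.

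Each region showed the dosage response of the interval. The slope of the interval mean was 0.586 in the olfactory bulb, 0.526 in the cortex, 0.507 in the cerebellum and 0.534 in the brain stem. The exact two-sided p was 0.00179 in each region with 8 mice and 0.00476 in the cortex with 7 mice, the smallest that 560 and 210 assignments can give. Within regions, 20, 19, 20 and 21 interval genes passed the threshold in that order, in a model with the mouse as a random block; the cerebellar count was 11 with array weights. Doc2a, a calcium sensor of neurotransmitter release, was the only measured interval gene whose slope differed between regions (limma F test, adjusted p = 0.0205). It was 0.675 ± 0.08 in the olfactory bulb, 0.632 ± 0.08 in the cortex and 0.784 ± 0.08 in the brain stem (SE, 7 or 8 mice), against 0.192 ± 0.08 in the cerebellum, which did not pass the threshold. Doc2a was also least expressed in the cerebellum, at 7.10 ± 0.13 log2 in +/+ mice, and its regional difference was no longer past the threshold without +/+ mouse 2, df/+ mouse 1, df/+ mouse 2, dp/+ mouse 1 or dp/+ mouse 2, each giving a count of 0. The count was also 0 with the slope on the copies themselves, without a block for the mouse and after cyclic loess normalisation.

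In wild-type brain, 16 of the 30 measured interval genes differed between the 4 regions (limma, 12 samples of 3 +/+ mice with the mouse as a block), as did 11567 of all 19938 genes. Doc2a ranged from 7.10 in the cerebellum to 9.76 ± 0.07 in the cortex (log2, SD, n = 3). Pagr1a was highest in the cerebellum, at 11.43 ± 0.22, and lowest in the olfactory bulb, at 9.91 ± 0.23. Gdpd3 was highest in the olfactory bulb, at 9.40 ± 0.35, and lowest in the cortex, at 7.69 ± 0.18. Kctd13 was at 10.38 ± 0.08 in the cortex and 9.45 ± 0.11 in the cerebellum. Sez6l2, a neuronal membrane protein, was at 11.27 ± 0.21 in the brain stem and 10.31 ± 0.32 in the olfactory bulb.

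The next comparison asked whether dosage of the interval was accompanied by changes elsewhere in the genome. No measured gene next to the interval passed the threshold: of the flanking genes, 21 of the 23 listed on the Slx1b side and 35 of the 37 listed on the Septin1 side were measured, and 0 had a dosage slope past the threshold over all genes or adjusted over the list alone (limma; 0 and 1 with an unadjusted p below 0.05; median slopes 0.02 and −0.003). On the Slx1b side, Atp2a1 had 0.09, Il4ra 0.07, Tufm −0.08 and Gtf3c1 −0.05, none past the threshold. On the Septin1 side, Zfp764 had −0.10, Sephs2 −0.08, Zfp553 −0.09 and Pycard 0.06, again none past it. With array weights 1 flanking gene passed.

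Across the brain, 1 gene outside the interval rose with dosage, the C-type lectin Cd209a, with a slope of 0.235 ± 0.04 (SE, n = 8 mice; adjusted p = 0.0410), and 1342 had an unadjusted p below 0.05. Both df/+ mice lay below the 3 +/+ mice and all 3 dp/+ mice above them. Cd209a was not past the threshold without +/+ mouse 1, +/+ mouse 3, df/+ mouse 1, df/+ mouse 2, dp/+ mouse 1, dp/+ mouse 2 or dp/+ mouse 3 (adjusted p 0.0707, 0.106, 0.230, 0.607, 0.194, 0.136 and 0.0913). The count outside the interval was 3 without +/+ mouse 2, 0 without +/+ mouse 3, df/+ mouse 1, df/+ mouse 2, dp/+ mouse 2 or dp/+ mouse 3, and 0 under every rescaling of the arrays, while it was 79 with a trended robust prior and 1588 with array weights.

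In df/+ mice, 4 genes outside the interval fell and 0 rose, with 1322 at an unadjusted p below 0.05. They were the small nucleolar RNA gene Snord35b, which fell by 0.57 ± 0.08 log2 (SE, n = 2; adjusted p = 0.0116), the Cajal body RNA gene Scarna17, which fell by 0.56 ± 0.08 (adjusted p = 0.0124), the vault RNA gene Vaultrc5, which fell by 1.28 ± 0.18 (adjusted p = 0.0147), and Mphosph6, whose product works in ribosomal RNA maturation with the exosome, which fell by 0.43 ± 0.07 (adjusted p = 0.0316). Both df/+ mice lay below all 3 +/+ mice for each. The dp/+ mice were also low for Snord35b (−0.52, −0.44 and −0.51 log2) and Scarna17 (−0.50, −0.34 and −0.54). For Mphosph6 they also lay below all 3 +/+ mice (−0.15, −0.17 and −0.26), while for Vaultrc5 they did not (−0.15, 0.07 and −0.49). The count was 1 without +/+ mouse 1, 0 without +/+ mouse 2, 11 without +/+ mouse 3, 8 without df/+ mouse 1, 2 without df/+ mouse 2 and 8 without dp/+ mouse 3. It was 0 adjusted over the genes outside the interval alone and 0 with a trended robust prior, but 11 with all region samples in a model with mouse as a random block and 19 without the cortex.

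In dp/+ mice, 356 genes outside the interval changed, 280 higher and 76 lower, with 4696 at an unadjusted p below 0.05. Most of the genes that rose were dim genes of sensory receptor families: of 1207 measured olfactory, vomeronasal and trace amine receptor genes, 185 rose and 0 fell. Olfr485 rose by 0.55 ± 0.06 log2 (SE, n = 3), Olfr1184 by 0.55 ± 0.06, Vmn2r-ps104 by 0.53 ± 0.06, Vmn1r193 by 0.42 ± 0.05 and Olfr1148 by 0.42 ± 0.05, each with an adjusted p of 0.00796. These rises across the brain came mainly from the olfactory bulb and cerebellum, and were smaller in the cortex and brain stem. In that order Olfr485 stood at 220%, 172%, 110% and 105% of +/+, and Olfr1184 at 195%, 171%, 104% and 113%. The dp/+ mice varied widely for Olfr1184 in the bulb and cerebellum (SD 0.75 and 0.72 log2, n = 3). The multigene families of Olfr, Vmn and Srsy genes share sequence, so which member gave each signal is uncertain. Some of them read near or below Xist in these males, as Olfr1184 did at 4.22 to 4.40 log2 in +/+ mice, and none was tested against background, so these differences are those on the scale of the array. Srsy rose by 1.02 ± 0.12, Gm7982 by 0.43 ± 0.05, the hair keratin-associated gene Krtap5-2 by 0.46 ± 0.06 and the microRNA gene Mir680-1 by 0.55 ± 0.07, while the small nucleolar RNA gene Snora31 fell by 0.82 ± 0.10, at the same adjusted p. The whole range of dim genes stood higher on dp/+ arrays: 256 of the 280 genes that rose (91.4%) lay in the lower 40% of expression, and the median change of all genes was 0.07 log2 in decile 1 of expression, the dimmest, and −0.07 in decile 8.

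The number of genes that changed in dp/+ mice depended on single mice and on the scale of the arrays. It was 738 without +/+ mouse 1, 8 without +/+ mouse 2, 52 without +/+ mouse 3, 220 without df/+ mouse 1, 220 without df/+ mouse 2, 113 without dp/+ mouse 1, 29 without dp/+ mouse 2 and 128 without dp/+ mouse 3. It was 76 after renewed quantile normalisation within regions (44 higher, 32 lower), 914 with arrays centred on their medians (841 higher, 73 lower), 62 after cyclic loess between arrays (35 higher, 27 lower) and 12 among brighter genes only (5 higher, 7 lower).

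In the olfactory bulb, 29 genes outside the interval had a dosage slope (limma, 1180 at an unadjusted p below 0.05). Of these, 22 fell with copy number and 7 had a positive slope. The neuromedin B receptor gene Nmbr had the smallest p, with a slope of −0.99 ± 0.12 (SE, n = 8 mice), at 178% of +/+ in df/+ mice and 59.8% in dp/+ mice. Mal2, a membrane trafficking protein, had −1.14 ± 0.17 (175% and 49.4%), the neuronal actin-binding protein gene Enc1 −0.96 ± 0.14 (156% and 53.9%), 6430553K19Rik −0.56 ± 0.08 (134% and 71.7%) and the sodium, calcium and potassium exchanger gene Slc24a2 −0.54 ± 0.07 (136% and 75.2%). Further neuronal genes that fell, chosen after their values were seen, were the cannabinoid receptor gene Cnr1 (−0.63 ± 0.10), the secreted proteins Tafa1 (−0.95 ± 0.15) and C1ql3 (−0.95 ± 0.15) and the neuropeptide somatostatin, Sst (−0.84 ± 0.17). In +/+ mice 20 of the 22 genes that fell were higher in the cortex than in the olfactory bulb. The 7 genes with a positive slope had low values in df/+ mice. In dp/+ mice they stood at 69.1% to 107% of +/+, so their slopes came from the low df/+ values. The steepest, also chosen after their values were seen, were the olfactory cytochrome P450 gene Cyp2g1 (slope 1.07 ± 0.23; 22.2% of +/+ in df/+ mice and 69.1% in dp/+ mice), the nasal secretoglobin gene Scgb1c1 (1.01 ± 0.18; 26.4% and 77.7%) and the glutathione peroxidase gene Gpx6 (0.92 ± 0.18; 31.9% and 85.0%). Cyp2g1 also varied between +/+ bulbs, from 7.20 to 9.05 log2. The 5 listed markers of olfactory sensory neurons had bulb slopes between −0.03 and 0.13, none past the threshold. These slopes do not show equal levels. Gng13 was at 54.8% of +/+ in df/+ mice and 59.1% in dp/+ mice, Stoml3 at 57.4% and 62.3% and Cnga2 at 67.7% and 76.5%. Omp was at 82% and 79%, and Adcy3 at 101% and 98.0%. No contrast of either genotype with +/+ was run within the bulb. The count in the olfactory bulb was 11 without df/+ mouse 2, 19 without dp/+ mouse 2 and 18 without dp/+ mouse 3, and without df/+ mouse 1 it held 1 gene with a positive slope and 36 with a negative slope. It was 44 with the slope on the copies themselves, 86 with array weights and 2 with the bulb fitted alone.

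In the cortex, 0 genes outside the interval passed the threshold (limma; 1061 at an unadjusted p below 0.05). Those with the smallest p were 2900005J15Rik, with a slope of 0.26 ± 0.06 (SE, n = 7 mice), the cold-inducible RNA-binding protein gene Rbm3, with 0.62 ± 0.15, and Frmd7, with 0.51 ± 0.13 (adjusted p 0.211, 0.211 and 0.248). The count was 1 without +/+ mouse 1, df/+ mouse 1 or dp/+ mouse 1, 1 after cyclic loess and 21 with array weights.

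In the cerebellum, 3 genes outside the interval passed (791 at an unadjusted p below 0.05). Igfbp5, a binding protein of insulin-like growth factors, fell with copy number, with a slope of −0.42 ± 0.06 (SE, n = 8 mice; adjusted p = 8.33e-05). It was at 10.89 ± 0.02 log2 in df/+ mice (SD, n = 2), 10.62 ± 0.06 in +/+ mice (SD, n = 3) and 10.22 ± 0.05 in dp/+ mice (SD, n = 3), or 121% and 76.0% of +/+, with no overlap between genotypes. Ostn, which encodes the peptide osteocrin, rose, with 0.62 ± 0.10 (adjusted p = 0.00185), as did Synpr, a synaptic vesicle protein, with 0.40 ± 0.08 (adjusted p = 0.0213). Ostn was not past the threshold without df/+ mouse 2 (adjusted p = 0.233) or dp/+ mouse 1 (0.0600), nor Synpr without df/+ mouse 2 (0.501), dp/+ mouse 1 (0.0600), dp/+ mouse 2 (0.158) or dp/+ mouse 3 (0.0610). Ostn was dim, at percentile 12.9 of all genes in +/+ brain, in the range that stood higher on dp/+ arrays. The count was 1 without dp/+ mouse 1 and 11 without dp/+ mouse 3, and 1 with the cerebellum fitted alone.

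In the brain stem, 3 genes outside the interval rose with copy number (438 at an unadjusted p below 0.05). They were Cga, the common subunit of pituitary glycoprotein hormones, with a slope of 0.90 ± 0.15 (SE, n = 8 mice; adjusted p = 0.00102), the fatty acid desaturase gene Fads2b, with 0.64 ± 0.11 (adjusted p = 0.00192), and Oxt, which encodes oxytocin, with 0.75 ± 0.15 (adjusted p = 0.0265). Cga and Fads2b were dim, at percentiles 13 and 7.46 of all genes in +/+ brain, in the range that stood higher on dp/+ arrays. In the brain stem, Cga ran from 5.92 to 7.46 log2 in dp/+ mice, against 5.94 to 6.37 in +/+ mice. Cga was not past the threshold without df/+ mouse 2 (adjusted p = 0.146). Oxt was not without +/+ mouse 1 (0.0760), +/+ mouse 3 (0.0734), dp/+ mouse 1 (0.0657) or dp/+ mouse 3 (0.121), and without df/+ mouse 2 its slope was 0.33 (adjusted p = 1.00). The count was 5 without +/+ mouse 2, 6 without df/+ mouse 1 and 1 without df/+ mouse 2, and 1 among brighter genes, 26 with array weights and 0 with the brain stem fitted alone.

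Slopes of 9 genes outside the interval differed between regions in a test of the difference itself (limma F test). For Nmbr (adjusted p = 0.000315), 6430553K19Rik (0.00142), Slc24a2 (0.00867), Mal2 (0.0132) and Enc1 (0.0132) the negative slope was in the olfactory bulb, and their slopes in the 3 other regions lay between −0.07 and 0.18 without passing the threshold there. For Igfbp5 (0.00142) the negative slope was in the cerebellum, and those elsewhere lay between 0.005 and 0.12. Tafa1 (0.0252), Cnr1 (0.0322) and Bpifb4 (0.0424), named because they complete the count, had their slopes in the olfactory bulb. The count was 0 without df/+ mouse 2, 1 without dp/+ mouse 2 and 4 without a block for the mouse.

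**Figure D3:**
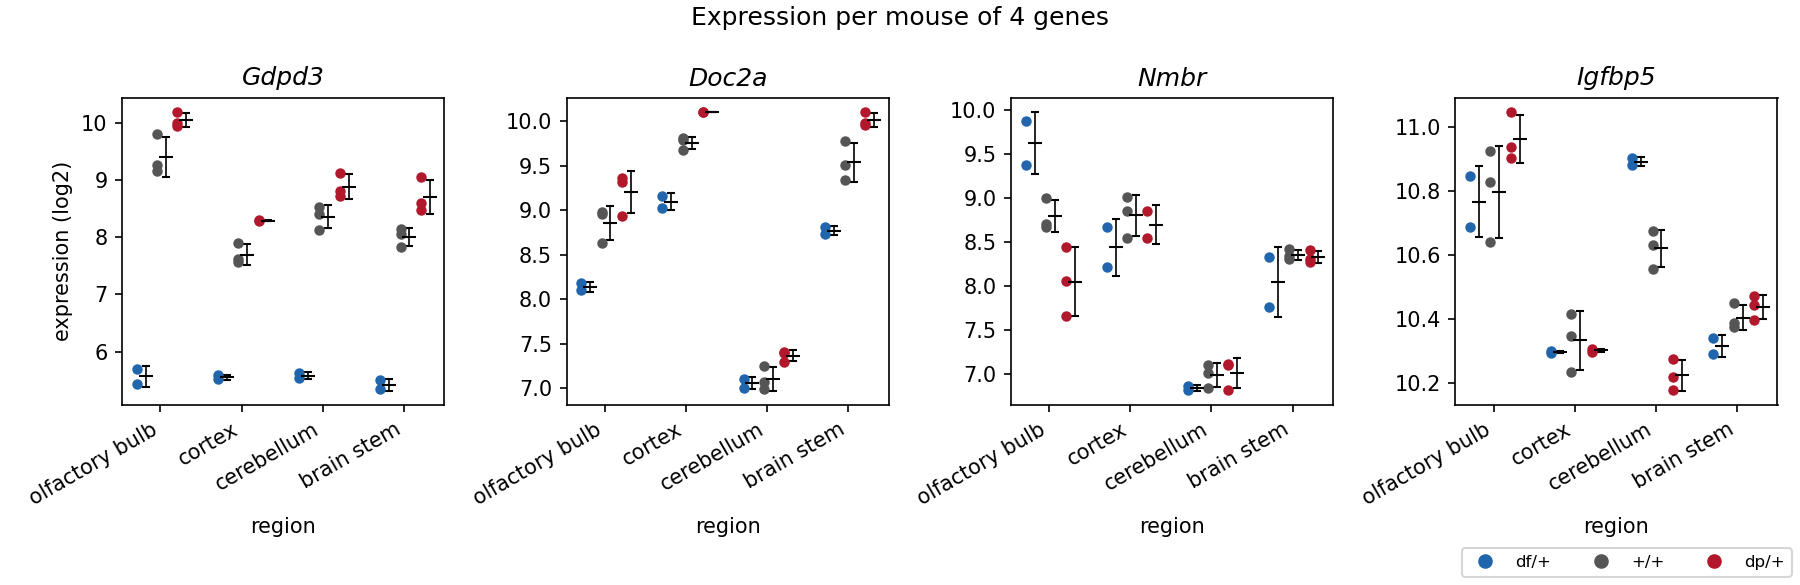
Expression (log2) of Gdpd3, Doc2a, Nmbr and Igfbp5 by region and genotype; points are mice, and bars beside them are the mean and SD. Gdpd3 is lowest in df/+ mice in every region, at 5.56 in the olfactory bulb, Doc2a has a slope of 0.192 in the cerebellum, and Nmbr and Igfbp5 fall with copy number in the olfactory bulb and the cerebellum.

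The last comparison asked whether groups of genes shifted together with dosage across the brain. Of 32 lists with enough measured genes, 6 were shifted relative to other genes with a preset correlation between genes (camera, adjusted p below 0.05), and 0 were with an estimated correlation. Neuronal genes were shifted lower with copy number (adjusted p = 0.00268; adjusted p = 0.169 with an estimated correlation). Among them the neurofilament genes Nefl and Nefm had slopes of −0.14 ± 0.04 and −0.20 ± 0.06 (SE, n = 8 mice). Genes of meningeal fibroblasts were shifted higher (adjusted p = 0.00268; adjusted p = 0.169 with an estimated correlation), with 0.19 ± 0.05 for Dcn and 0.17 ± 0.05 for Col1a2. The glutamatergic synapse was shifted lower (adjusted p = 0.00332; adjusted p = 0.478 with an estimated correlation), with −0.12 ± 0.03 for the receptor subunit Gria3 and −0.14 ± 0.04 for the transporter Slc17a6. Oxidative phosphorylation (0.0167), heat shock proteins (0.0215) and GABAergic neurons (0.0335) were shifted lower too, with an adjusted p of 0.671, 0.478 and 0.478 with an estimated correlation. Their medians were −0.06, −0.08 and −0.06 log2 in dp/+ mice and 0.002, −0.005 and 0.02 in df/+ mice. In dp/+ mice, genes outside the interval in deciles 6 to 9 of expression had similar medians (−0.05 to −0.08). Whether that difference between arrays gave the list shifts was not tested. The heat shock median was 0.003 in dp/+ mouse 1, against −0.16 and −0.11 in dp/+ mice 2 and 3. The count of lists was 1 by fry (neurons), which tests whether a list moves on balance 1 way, and 3 without the cortex or after cyclic loess.

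No single gene of these 32 lists passed the threshold for the slope across the brain (limma; 0 of 302, 28 with an unadjusted p below 0.05), and 10 passed adjusted over the list alone. The 26 other lists had adjusted p between 0.0900 and 0.745. Among them were targets and members of the ERK pathway (0.0900 and 0.108), the Cul3 and RhoA pathway (0.485), autism risk genes (0.198), proliferation genes (0.520) and the glial cell types. Examples that did not pass over all genes are Dlx1 of the olfactory bulb list (slope 0.26 ± 0.05), Nefh of the brain stem list (−0.18 ± 0.04) and the dopa decarboxylase gene Ddc of the dopamine list (0.17), each past the threshold adjusted over the list alone. Against +/+ mice alone, Clic6 of the choroid plexus (−0.44 ± 0.08 log2, adjusted p = 0.0253), Sst (−0.44 ± 0.08, 0.0226), the heat shock gene Dnajb1 (−0.42 ± 0.08, 0.0299) and the glucocorticoid target Tsc22d3 (−0.44 ± 0.09, 0.0404) fell in dp/+ mice (SE, n = 3). The median of the choroid plexus list was low in every mutant mouse, at −0.44 and −0.22 log2 in df/+ mice and −0.12, −0.42 and −0.28 in dp/+ mice, against −0.06 to 0.08 in +/+ mice. Tsc22d3 was also at −0.35 log2 in df/+ mouse 2, and the median of the glucocorticoid list was −0.40 in df/+ mouse 2, −0.50 in dp/+ mouse 2 and −0.70 in dp/+ mouse 3, against −0.09 in df/+ mouse 1, −0.20 in dp/+ mouse 1 and −0.17 to 0.07 in +/+ mice.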

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

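The test of cortex carried into the olfactory bulb samples was chosen only after the result was seen; the tests of regional differences in slope were planned. Slopes on copy number differed between regions for 10 genes, which is what sets these results apart. The adjusted p was 0.000315 for Nmbr, 0.00142 for 6430553K19Rik, 0.00867 for Slc24a2, 0.0132 for Mal2, 0.0132 for Enc1, 0.0252 for Tafa1 and 0.0322 for Cnr1, all with a negative slope in the olfactory bulb. It was 0.0424 for Bpifb4, whose positive slope of 0.54 was in the olfactory bulb, 0.00142 for Igfbp5, with its slope of −0.42 in the cerebellum, and 0.0205 for the interval gene Doc2a, with its low slope of 0.192 in the cerebellum.

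The bulb genes that fell with copy number form a pattern of 22 genes, 20 of them higher in the cortex than in the bulb of +/+ mice. Cortex carried into bulb samples in amounts that drop with copy number was examined as their source. A comparison with other cortex-rich genes cannot decide this for all 22, since its yardstick, Mal2, had the steepest slope among them. The 6 other genes with at least the cortex excess of Mal2 (3.13 log2) had a median bulb slope of −0.205. The steepest was −0.50 ± 0.17 (SE), against −1.14 ± 0.17 for Mal2. Only Ttr, of the choroid plexus list, was positive (0.21 ± 0.50), so a part from cortex stays open. Of the listed cortex markers Tbr1 had −0.51 ± 0.34, Neurod6 −0.06 ± 0.30 and Emx1 −0.03 ± 0.09, none past the threshold. Cortex could not raise Nmbr, at 8.79 in the bulb and 8.80 in the cortex of +/+ mice, to the 9.62 of the df/+ bulb. Nor could it raise 6430553K19Rik, at 7.30 in the bulb and 4.64 in the cortex. For Nmbr and 6430553K19Rik, cortex is thus argued against as the sole source. A shift of dim genes is argued against, since 4.55% of the 22 (1 gene) lay in the lower 40% of expression and all 29 bulb genes kept their call among 33 after cyclic loess. A difference between genotypes in bulb neurons, or in how much of the adjoining olfactory tissue was dissected with the bulb, may account for it. Both stay open. The listed markers of olfactory sensory neurons bear on nasal tissue alone, and brain tissue next to the bulb was not profiled here. Slopes of these markers were near 0 (Omp −0.02, Stoml3 0.10 and Cnga2 0.13, none past the threshold). A slope cannot show a level that is low in both mutant genotypes, as it was for Gng13 and Stoml3 but not for Adcy3.

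Outside the genes compared in the report, 4 probe sets without a single gene symbol also had a dosage slope past the threshold, 2 of them with several symbols and 2 with no listed gene. Their slopes ran from −0.38 to 0.72, and 3 were positive.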

How the results depend on the processing

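The slopes of the interval mean kept their direction in every alternative run. Of the values of the main results, 385 lay within 1.5 times the reported count or within the spread between mice; the 86 others are given here, and the cause was not tested for any. Directions within a count moved too: genes changed in dp/+ mice, 280 higher and 76 lower, were 5 higher and 7 lower among brighter genes and 66 higher and 0 lower with the trended robust prior, bulb genes, 7 rising and 22 falling, were 37 rising and 49 falling with array weights, and the slope across the brain, with 1 rising gene, had 2 rising and 4 falling with all region samples and 0 rising and 1 falling without the cortex or without +/+ mouse 1. Of the values of single genes, 3525 were the same, 70 were no longer past the threshold, 47 came to pass it and 0 reversed. The slope of the interval mean lay between 0.527 and 0.540 with each mouse left out, and the count of 21 interval genes between 19 and 21.

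Genes outside the interval with a slope across the brain numbered 0 with every probe set, brighter genes only, renewed quantile normalisation, centred arrays, the replicate block, cyclic loess or adjustment over the outside genes alone, 79 with a trended robust prior, 1588 with array weights and 6 with all region samples. Those changed in df/+ mice numbered 0 with the trended robust prior or adjusted over outside genes alone, 11 with all region samples and 19 without the cortex. Those changed in dp/+ mice numbered 12 among brighter genes, 76 after renewed quantile normalisation, 914 with centred arrays, 66 with the trended robust prior, 2196 with array weights, 1009 with all region samples, 27 with the biological number as a replicate block and 62 after cyclic loess. Interval genes changed in dp/+ mice numbered 8 among brighter genes, 26 with array weights and 4 with the replicate block.

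Within regions, array weights gave 86 genes outside the interval in the olfactory bulb, 21 in the cortex and 26 in the brain stem, 11 interval genes in the cerebellum and 1 flanking gene. The bulb count was 44 with the slope on copies and 2 with each region fitted alone, where the cerebellum had 1 and the brain stem 0; among brighter genes the brain stem had 1, and after cyclic loess the cortex had 1. Slopes that differ between regions numbered 0 interval genes with the slope on copies, without a block for the mouse or after cyclic loess, and 4 outside genes without that block. Lists shifted with dosage numbered 3 without the cortex or after cyclic loess, 0 with an estimated correlation and 1 by fry.

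With each mouse left out in turn, outside genes ranged from 0 to 3 for the slope across the brain, 0 to 11 in df/+, 8 to 738 in dp/+, 11 to 39 in the olfactory bulb, 0 to 1 in the cortex, 1 to 11 in the cerebellum and 1 to 6 in the brain stem. Interval genes changed in dp/+ ranged from 3 to 16. Slopes that differ between regions ranged from 0 to 1 in the interval and 0 to 10 outside it.

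The replicate numbers do not pair mice: correlations across genes between mice of equal number and different genotype, after removal of the genotype mean, were −0.274, 0.173, −0.217, −0.382, −0.0181, 0.120 and −0.155, and genes are not independent replicates. The 9 interval genes short of the threshold had a median level at percentile 35 of all genes, against 67.1 for the others, with 4930451I11Rik the highest of them at 54.7 and Hirip3 the lowest of the others at 37.9.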

Other observations

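The tests of differences between mice of 1 genotype, of dim genes on dp/+ arrays and of neighbouring genes were chosen only after the results were seen, as was every gene named in this part; the tests of other assignments of the samples were planned. Mice of 1 genotype differed from each other across their regions for 542 genes outside the interval (limma F test between mice, 130 below an adjusted p of 0.01, 3919 with an unadjusted p below 0.05). Some genes known to respond to glucocorticoids or to follow the daily rhythm were among them, and others were not; neither group was tested for enrichment. Sgk1 lay at −0.84 log2 in df/+ mouse 2, −0.50 in dp/+ mouse 2 and −0.999 in dp/+ mouse 3, and between −0.16 and 0.07 in the 5 other mice. Per1 lay at −0.49, −0.34 and −0.70 in those 3 mice, Pdk4 at −0.64, −0.79 and −0.80, and Hif3a at −0.48, −0.48 and −0.60. The adjusted p between mice missed the threshold for Tsc22d3 (0.0843), Zbtb16 (0.0612), Per3 (0.235), Nr1d1 (0.549), Nr1d2 (0.385), Arntl (0.118), Tef (0.0898) and Hlf (0.606). Neither Sgk1 nor Per1 had a slope on copy number past the threshold (adjusted p 0.952 and 0.95).

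Small nucleolar and Cajal body RNA genes, chosen for their values, had low medians in the mutant mice, although few passed the threshold. The median over 54 such genes was −0.20 and −0.30 log2 in the df/+ mice, −0.33, −0.16 and −0.21 in the dp/+ mice, and −0.04, 0.09 and −0.06 in the +/+ mice. Both mutant genotypes are measured against the same 3 +/+ mice, and no test of the group was run. In dp/+ mice 10 of the 54 were called lower and 1 higher. The 3 Cajal body RNA genes varied between mice, with medians of −0.18 and −0.12 in df/+, 0.02, 0.08 and −0.19 in +/+, and −0.25, −0.19 and 0.05 in dp/+ mice. The coat colour gene Tyr, for tyrosinase, lay at 0.26 and 0.39 in df/+ mice, −0.40, 0.16 and 0.24 in +/+ mice and −0.37, −0.36 and −0.35 in dp/+ mice (adjusted p = 0.00173 between mice of 1 genotype). The kallikrein gene Klk1b22 ranged from −1.54 to 1.54 between the dp/+ mice.

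The rise of many genes in dp/+ mice coincided with a higher level of dim genes. The median change of receptor genes was at least 0.135 log2 in each dp/+ mouse, against −0.02 to 0.03 in +/+ mice, and the number of changed genes was 62 after cyclic loess, with 60 of them among the 356, so part of it may come from a rise of dim probe sets or an intensity-dependent difference that normalisation removes. The median change of receptor genes was 0.0890 log2 above that of other genes of the same level. The per-mouse medians were 0.15, 0.14 and 0.16 in dp/+ mice against 0.07, 0.05 and 0.05 for those other genes. After cyclic loess the receptor medians were still 0.08, 0.07 and 0.12 in dp/+ mice, against −0.01 to 0.01 in +/+ mice. A change in these probe sets beyond the dim-gene rise therefore stays open. Of the 10 splits of the 6 +/+ and dp/+ mice, the real one (1 split) gave 356 genes and the highest other 0; these splits are too few for a share under 0.05. A difference between array batches cannot be tested, since the labels give none.

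The genes that differ between mice lie next to each other more often than random sets drawn from all placed genes. These sets were not matched for expression level. They therefore cannot tell such an excess from clustering of genes expressed at similar levels. There were 24 neighbouring pairs, against a median of 15 and a highest count of 33 in 10000 random sets (permutation p = 0.01). Of 20 runs of such neighbours, 1 on chromosome 7, with Ccdc106, U2af2 and Epn1, was high in dp/+ mouse 1 (0.43, 0.32 and 0.41 log2). So was the longer chromosome 7 run of Zfp579, Fiz1, Zfp524 and Zfp865 (0.38, 0.35, 0.26 and 0.39). Members of some other runs moved in opposite directions. In df/+ mouse 2 and dp/+ mouse 3, Taf10 was at 0.24 and 0.25 and Tpp1 at −0.30 and −0.34. Likewise Snord8 was at 0.25 and 0.39 and Rab2b at −0.29 and −0.25. Dag1 and Nicn1 fell together there (−0.19 and −0.25, −0.22 and −0.24). Probe sets of related neighbours reading each other are argued against for most pairs, since 22 of the 24 had no shared name stem. The median of such pairs in the same unmatched random sets was 13 (permutation p = 0.00900). Chromosomal segments that differ between the mice may be 1 source, although the design text calls the genomes identical outside the engineered segment; genes regulated together by neighbourhood stay open and were not tested.

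Of 100 assignments of the genotypes to the 8 mice, the real one included, 3 gave as many genes with a slope as the real 22. That share is under 0.05, but it does not exclude chance, since the others gave far more genes than the real one. Of the real 22, 21 were interval genes, so the count says nothing of the 1 gene outside the interval. The highest other count was 71 and the next 60, with 0 interval genes in both. Both put df/+ mouse 2 and dp/+ mouse 3 together as the mice with 1 copy. Counts several times the real one point to a structure of the samples apart from genotype; which structure was not tested. For regional differences of interval genes in +/+ mice, 100 assignments of the regions within mice were compared, the real one included. Only the real one (1 of 100) gave 16 genes, and the highest other gave 8, which argues against chance for that count.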
